A study of Danio rerio with 18 samples.

How the data were processed

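RNA from FACS-sorted zebrafish embryo cells was measured in 18 libraries. Per the labels, total RNA was extracted with a Trizol-based column method including DNase, and libraries were made with the SMARTer low input kit. The labels give the stage, the GFP status and the genetic background of each library. They name the gene of a genetic background and not the allele, and they do not name the reporter behind GFP. Replicates 1 and 2 of a group are not said to be separate pools of embryos. They may be technical, so every p-value measures only the spread between these libraries.

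The deposited counts are whole-number reads per Ensembl gene ID and library, with no normalization. The deposited log2 values are regularized-log values on the same libraries, made with DESeq2 per the submitters' processing notes, which give no version for it. The same notes list Trimmomatic 0.36, STAR 2.5, SAMtools 1.4 and genome build GRCz10. The counting step, the annotation release and the strand setting are not given in the sources used here. Reads of antisense or overlapping genes, and of near-identical paralogs, can therefore not be assigned with certainty. Library totals ran from 5705157 to 32141901 counts. Intervals and floors given for low counts cover counting error only, at 95% confidence. The floor is 3 counts, per library for a single library and over the group for a fold change.

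The counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter by group (minimum count 10, minimum total 15), robust dispersion estimates and the robust quasi-likelihood F test. The test is two-sided, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. GFP-positive and GFP-negative libraries were compared within condition, over all 18 libraries and 21729 genes with 11 residual degrees of freedom. Stage and genotype comparisons used the 12 GFP-positive libraries as 6 groups, with 23767 genes and 6 residual degrees of freedom. Interactions used all libraries as 12 groups, with 26357 genes and 6 residual degrees of freedom. In that fit each GFP-negative group is 1 library, which is assumed to vary like the GFP-positive groups. Common biological coefficients of variation were 0.822, 0.89 and 0.866 in these fits.

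Gene symbols came from a reference table of gene IDs and symbols, which gave a symbol for 24555 of 28298 IDs. 11717 IDs carry an upper-case symbol, and 3559 IDs share their symbol with another ID. Such a symbol can stand for more than 1 zebrafish paralog, and the split of reads between paralogs is uncertain. Gene lists for cardiac identity and function, metabolism, growth, stress, matrix and other cell types, 29 in all, were fixed before the data were examined, as were the comparisons, the tests, the planned settings and the rule for naming genes. List members were matched exactly (221), ignoring case (209), by a changed dot (1), by a synonym (9), through a shared paralog symbol (97) or by a name pattern (268), and 84 were not matched. Lists of xanthophore, iridophore and melanophore genes were added after seeing the data. The result of 1 of the fixed lists and those of 1 gene that the naming rule picks are not reported here.

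Lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01. Adjustment ran over the lists of a comparison. Each camera call was repeated with an estimated correlation and with fry. Camera sets a list against all other genes, and fry asks whether a list's genes move one way. Counts of list members are given over all genes tested and adjusted over the list alone.

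The targeted genes are given in every library. The named genes are the 12 largest log2 fold changes in each direction among called genes with a mean of at least 10 CPM in the higher group, compared libraries that do not overlap, and a proper name as symbol. For pairwise genotype contrasts and interactions, 5 are taken in each direction. From each called list the 3 called members with the largest change are added. nkx2.5, gata4, gata6, tbx20, mef2ca, hey2, nppa, myl7, myh6 and vmhc are named in each of the 7 main comparisons whatever their values. mef2ca matched MEF2C, which 2 gene IDs carry, and vmhc matched MYH7. Only part of the genes that meet the rule are named in the text.

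The scripts were tested on simulated data with the real means and library sizes and 200 genes changed by 2, 4, 8 or 16 times, 50 each. For the GFP comparison, 77 genes were called, of which 2 were false (2.6%), and 2, 19, 25 and 29 changed genes were recovered at the 4 fold sizes. For 48 against 24 hpf, 69 were called with 8 false (11.6%), and 0, 11, 22 and 28 were recovered. For gata5 against wild type, 43 were called with 8 false (18.6%), and 0, 6, 10 and 19 were recovered. For the stage by GFP interaction, 51 were called with 31 false (60.8%), and 0, 3, 6 and 11 were recovered. No gene was called in the wrong direction. The false shares of the stage, genotype and interaction tests lie above the nominal level, so a bias-adjusted quasi-likelihood fit was added after seeing this. It called 4 genes with 0 false in the simulated interaction, 110 with 12 false in the simulated GFP comparison, and 69 with 8 false and 43 with 8 false in the other two. Of 28 unchanged lists, camera called 0 in each simulation. Genes were simulated independently and these lists were random, so this does not check list calls where genes of a list vary together.

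The planned settings were RLE scaling, the DESeq2 1.42.0 Wald test, limma on the deposited log2 values, no low-count filter, subsets of the libraries, all libraries as 12 groups, no condition covariate, a fold minimum of 2, the replicate number as a block, each library left out in turn, and the estimated correlation. Settings added after seeing the data were the sarcomere or the xanthophore level as a covariate, the fit without 2 libraries with low cardiac markers (gata5 replicate 2 and wild-type 72 hpf replicate 2), the GFP comparison without the 24 hpf libraries, and the bias-adjusted fit. Tables were handled with pandas 2.3.3 and figures drawn with matplotlib 3.10.9. GFP-negative libraries of different conditions were compared without a test, since each condition has 1.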

Results

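Zebrafish embryo cells were sorted into a GFP-positive and a GFP-negative fraction, and their RNA was sequenced in 18 libraries. Wild-type embryos were sampled at 24, 48 and 72 hpf (hours post fertilization), and embryos of the gata5, tbx5 and hand2 backgrounds at 72 hpf. Each of these 6 conditions had 2 GFP-positive libraries and 1 GFP-negative library. GFP-positive replicates 1 and 2 held 12070094 and 16272092 counts at 24 hpf, 16696417 and 20761818 at 48 hpf and 23617376 and 32141901 at 72 hpf in wild type, 13385207 and 14098557 in gata5, 30871617 and 19493256 in tbx5, and 27680568 and 24654136 in hand2. The GFP-negative libraries held 6771770, 8627731 and 5705157 counts in wild type at 24, 48 and 72 hpf, 6397704 in gata5, 18863332 in tbx5 and 8756123 in hand2. Across genes, which are not independent replicates, log2 levels of replicates 1 and 2 correlated with r = 0.85 at 24 hpf, 0.927 at 48 hpf, 0.742 at 72 hpf, 0.84 in gata5, 0.907 in tbx5 and 0.944 in hand2. The most abundant gene ID, ENSDARG00000080337, has no symbol and took 7.51 to 10.6% of the counts in the GFP-negative libraries and up to 26.3% in the GFP-positive ones. Values in parentheses after a gene are log2 fold changes ± SE from edgeR, and levels are TMM-scaled CPM.

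The genes that name the genetic backgrounds encode transcription factors of early heart development, and their transcripts check the labels. HAND2 (ENSDARG00000008305) was nearly gone in the hand2 libraries. It stood at 2.56 CPM (61 counts) in GFP-positive replicate 1, at 0 in replicate 2, where 3 counts would be 0.147 CPM, and at 0 in the GFP-negative library, where 3 counts would be 0.304 CPM. All other libraries held HAND2, at 47.2 and 45.8 CPM in GFP-positive wild type at 72 hpf, 107 and 123 at 48 hpf, 91.7 and 70.18 at 24 hpf, 22.5 and 22.1 in gata5, 19.2 and 22.1 in tbx5, and 11.3 to 47.7 in the GFP-negative libraries. The edgeR test of hand2 against wild type did not call it (−5.15 ± 1.15, adjusted p = 0.212, n = 2 against 2).

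GATA5 (ENSDARG00000017821) remained in the gata5 libraries, at 17.1 and 14.0 CPM in GFP-positive cells, against 22.1 and 37.3 in wild type at 72 hpf, 18.8 and 18.1 in tbx5 and 47.7 and 17.7 in hand2. In GFP-negative cells its level in gata5, 14.9 CPM, was above the 1.52 to 6.81 CPM of the other 5 libraries. Wild-type GFP-positive cells held 71.7 and 54.5 CPM at 24 hpf and 67.8 and 125 at 48 hpf. TBX5 (ENSDARG00000024894, tbx5a) was at 15.5 and 5.18 CPM in tbx5 GFP-positive cells, inside the range of gata5 (17.2 and 1.23) and near hand2 (15.6 and 9.51) and wild type (15.4 and 21.7). At 24 hpf it stood at 13.4 and 19.3 CPM and at 48 hpf at 39.7 and 46.5. The GFP-negative libraries held 6.42, 10.6 and 20.6 CPM in wild type, 31.1 in gata5, 4.32 in tbx5 and 6.38 in hand2. Its paralog tbx5b did not exceed 2.82 CPM in any library. Neither GATA5 in gata5 (−0.95 ± 0.47, adjusted p = 0.536) nor TBX5 in tbx5 (−0.84 ± 0.86, adjusted p = 0.837) was called, so transcript levels check the hand2 label and leave the gata5 and tbx5 labels unchecked.

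**Figure D1:**
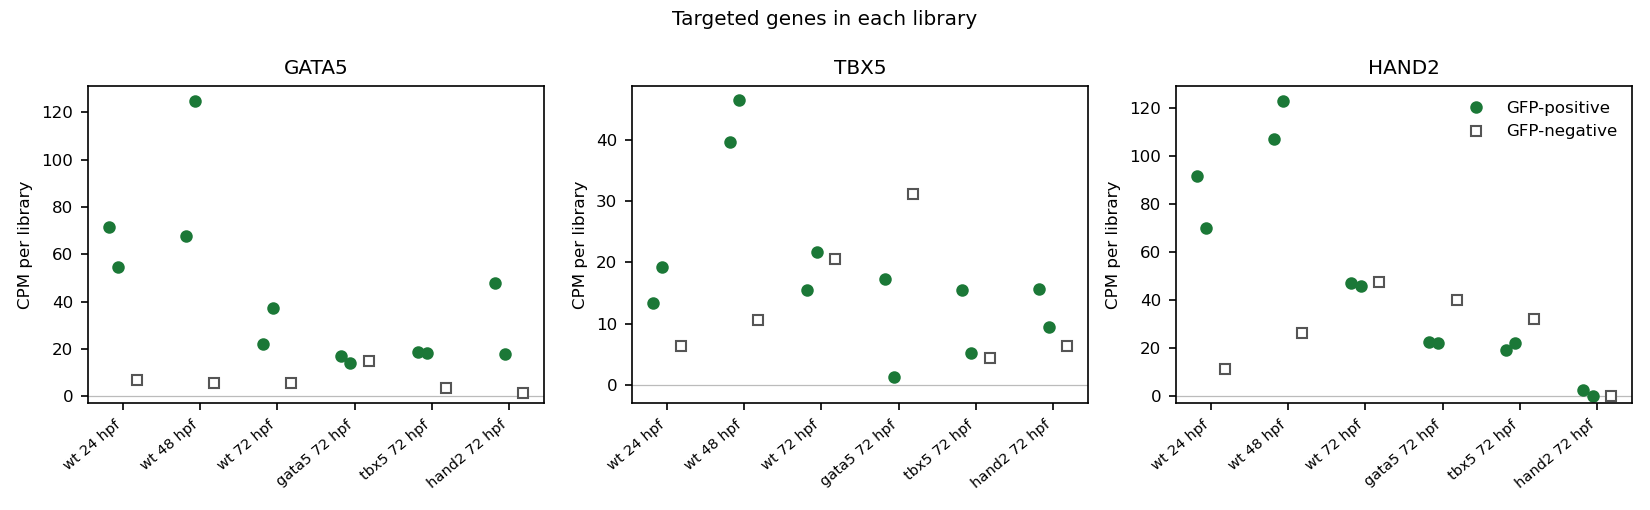
Levels of GATA5, TBX5 and HAND2 in CPM (y axis) in each library, by condition (x axis), with filled circles for GFP-positive and open squares for GFP-negative libraries. HAND2 lies at or below 2.56 CPM in the 3 hand2 libraries and at 11.3 CPM or more in every other library.

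The series concerns the cardiomyocyte transcriptome during heart development, and the first comparison asked which transcripts the GFP-positive fraction held above the rest of the embryo, with 12 GFP-positive against 6 GFP-negative libraries. Cardiac contractile genes stood far above the GFP-negative level. myh6, the atrial myosin heavy chain, averaged 158 CPM against 0.504 (8.0 ± 1.1, adjusted p = 0.000153), and MYH7, the symbol that matched the ventricular chain vmhc, 332 against 2.93 (6.82 ± 1.15). MYL7, the cardiac myosin light chain, stood at 127 against 2.35 CPM (5.0 ± 0.96), and the light chain gene cmlc1 at 202 against 0.997 (7.85 ± 1.19). TNNT2, cardiac troponin T, was 1540-fold higher by pooled counts (counting interval 426 to 12700), and nppa, atrial natriuretic peptide, 2660-fold (478 to 105000). In the cardiac sarcomere list 14 of 21 members rose and 0 fell, 16 and 0 adjusted over the list alone, with a median of 2.45 (camera adjusted p = 3.92e-11, adjusted p = 0.11 with an estimated correlation). Of the natriuretic peptide list 2 of 5 rose, also adjusted over the list alone (median 1.04, adjusted p = 0.0285, adjusted p = 0.228 with an estimated correlation), nppb among them (5.16 ± 1.42). Cardiac transcription factors moved both ways, 7 of 23 up and 6 down, and their list was not called (adjusted p = 0.596). GATA5 (2.61 ± 0.50), gata4 (3.06 ± 0.78), GATA6 (2.06 ± 0.73), NKX2-5 (3.47 ± 1.19) and TBX20 (1.43 ± 0.39) rose. HAND2 (0.66, adjusted p = 0.503), TBX5 (0.50, adjusted p = 0.534), HEY2 (0.51, adjusted p = 0.461) and the pair of MEF2C IDs (0.42 and 0.44) were not called. Calcium handling and ion channel genes had 5 of 21 members up and 5 down, 8 and 6 adjusted over the list alone, with a median of −0.02, a mean of 0.11 and no call (adjusted p = 0.31).

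Energy metabolism genes were higher in the GFP-positive fraction. That fraction also held xanthophore genes, given below, at summed levels of 14700 to 54400 CPM in its 48 and 72 hpf libraries. Which of its cells carry this difference, or those in growth and stress genes, was not tested. Of the nuclear oxidative phosphorylation list 38 of 103 rose and 0 fell, 42 and 0 adjusted over the list alone (median 0.64, adjusted p = 5.46e-09, adjusted p = 0.146 with an estimated correlation), for example the complex I gene ndufc2 (1.17 ± 0.28) and cytochrome c, cycsb (1.12 ± 0.18). All 13 mitochondrially encoded transcripts were called adjusted over the list alone, and 11 over all genes (median 1.24, adjusted p = 1.59e-08, adjusted p = 0.146 with an estimated correlation). MT-CO1 averaged 8770 against 3200 CPM. Fatty acid oxidation genes rose in 15 of 27 and fell in 0, 15 and 1 adjusted over the list alone (median 0.87, adjusted p = 1.74e-07, adjusted p = 0.11 with an estimated correlation). CPT1B, which brings fatty acids into mitochondria, was among them (3.11 ± 0.49), as was ACSL1 (1.85 ± 0.32). Glycolysis genes rose in 11 of 27 and fell in 2, 12 and 3 adjusted over the list alone (median 0.83, adjusted p = 0.000551, adjusted p = 0.228 with an estimated correlation). GAPDH rose (2.71 ± 0.42) while the enolases eno2 (−3.28 ± 0.71) and ENO1 (−4.22 ± 1.48) fell.

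Growth and stress genes moved as groups too. Ribosomal protein genes rose in 53 of 93, 62 adjusted over the list alone, and fell in 0 (median 0.63, adjusted p = 3.92e-11, adjusted p = 0.296 with an estimated correlation). Ribosome biogenesis genes rose in 4 of 26, 0 adjusted over the list alone (median 0.17, adjusted p = 0.0484, adjusted p = 0.577 with an estimated correlation). Cell cycle genes fell in 23 of 47 and rose in 0, 26 and 0 adjusted over the list alone (median −0.61, adjusted p = 0.000381, adjusted p = 0.342 with an estimated correlation), including the proliferation marker mki67 (−1.14 ± 0.17). Immediate early genes, which respond to cell handling and other stimuli within minutes, rose in 10 of 21, 12 up and 1 down adjusted over the list alone (median 1.35, adjusted p = 5.96e-05, adjusted p = 0.342 with an estimated correlation). Heat shock and unfolded protein response genes rose in 8 of 23, 10 adjusted over the list alone (median 0.53, adjusted p = 0.00149, adjusted p = 0.146 with an estimated correlation). Circadian clock genes were not called as a list (8 of 20 up, 4 down, adjusted p = 0.0919).

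Markers of other cell types differed widely between the fractions. Neural genes fell in 19 of 21 members and rose in 0, 20 and 0 adjusted over the list alone (median −2.74, adjusted p = 1.05e-13, adjusted p = 0.0495 with an estimated correlation). ELAVL3, an RNA-binding protein of neurons, averaged 37.2 against 292 CPM (−3.11 ± 0.15). Collagens fell in 38 of 55, 43 adjusted over the list alone (median −1.89, adjusted p = 1.68e-17, adjusted p = 0.0495 with an estimated correlation). Cartilage and notochord genes fell in 14 of 16, 15 adjusted over the list alone (median −2.39, adjusted p = 3.74e-09, adjusted p = 0.11 with an estimated correlation), COL11A2 among them (−3.0 ± 0.53). Epicardium and fibroblast-like genes fell in 16 of 23, 17 down and 1 up adjusted over the list alone (median −1.32, adjusted p = 5.36e-08, adjusted p = 0.11 with an estimated correlation), col1a1a among them (−2.49 ± 0.22). Lens and retina genes fell in 7 of 19, the same number adjusted over the list alone (median −1.87, adjusted p = 0.00117, adjusted p = 0.146 with an estimated correlation). Large falls were also seen for HMX3 (−7.00 ± 1.41), NKX2-2 (−4.67 ± 1.26) and the potassium channel KCNJ6 (−4.61 ± 0.79).

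Some markers of other cells rose in the GFP-positive fraction. In the xanthophore list, added after seeing the data, 20 of 22 genes rose and 0 fell, the same adjusted over the list alone (median 5.52, adjusted p = 1.75e-15, adjusted p = 0.14 with an estimated correlation). gch2, which starts pteridine pigment synthesis, averaged 12300 CPM (SD 5520, n = 10) in GFP-positive libraries at 48 and 72 hpf, 121 in those at 24 hpf (n = 2) and 22.4 in GFP-negative libraries (n = 6). For aox5 these levels were 3730, 54.2 and 13.2 CPM, and for plin6, the gene with the largest rise of the comparison (11.42 ± 1.75), 676, 2.0 and 0.184 CPM. Leukocyte genes rose in 10 of 18 and fell in 1, 11 and 2 adjusted over the list alone (median 2.56, adjusted p = 5.46e-09, adjusted p = 0.0712 with an estimated correlation), with csf1ra (5.83 ± 0.75), a receptor also used by xanthophores, at 2090 CPM in GFP-positive libraries at 48 and 72 hpf, and the macrophage receptor gene marco (4.20 ± 0.48). Liver, yolk and gut genes rose in 10 of 23, 13 up and 1 down adjusted over the list alone (median 2.60, adjusted p = 1.67e-05, adjusted p = 0.146 with an estimated correlation), tfa, transferrin, among them (3.47 ± 0.46). The lists of erythrocytes (2 up and 11 down of 16, adjusted p = 0.0763), endothelium and endocardium (2 and 4 of 24, adjusted p = 0.707), smooth muscle (1 and 1 of 7, adjusted p = 0.441), atrioventricular canal (0 and 4 of 11, adjusted p = 0.051), skeletal muscle (0 and 1 of 25, adjusted p = 0.162), epidermis (1 and 1 of 25, adjusted p = 0.895), iridophores (4 and 1 of 10, adjusted p = 0.192) and melanophores (1 and 1 of 9, adjusted p = 0.839) were not called. Adjusted over the list alone, erythrocyte genes counted 2 up and 14 down. Neither were neural crest and pigment genes, whose median (−0.35) and mean (0.63) differed in sign (3 up and 1 down of 13, adjusted p = 0.218). For melanophore genes the median (−0.52) and the mean (0.22) differed in sign too.

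Of 21729 genes tested, 6363 passed, 2699 higher and 3664 lower in GFP-positive cells, where the median of all genes was −0.26. Among the 9 wild-type libraries alone 686 genes passed, of which 673 were also called over all libraries. Camera called 19 of the 29 fixed lists, and 3 of these calls held with an estimated correlation.

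**Figure D2:**
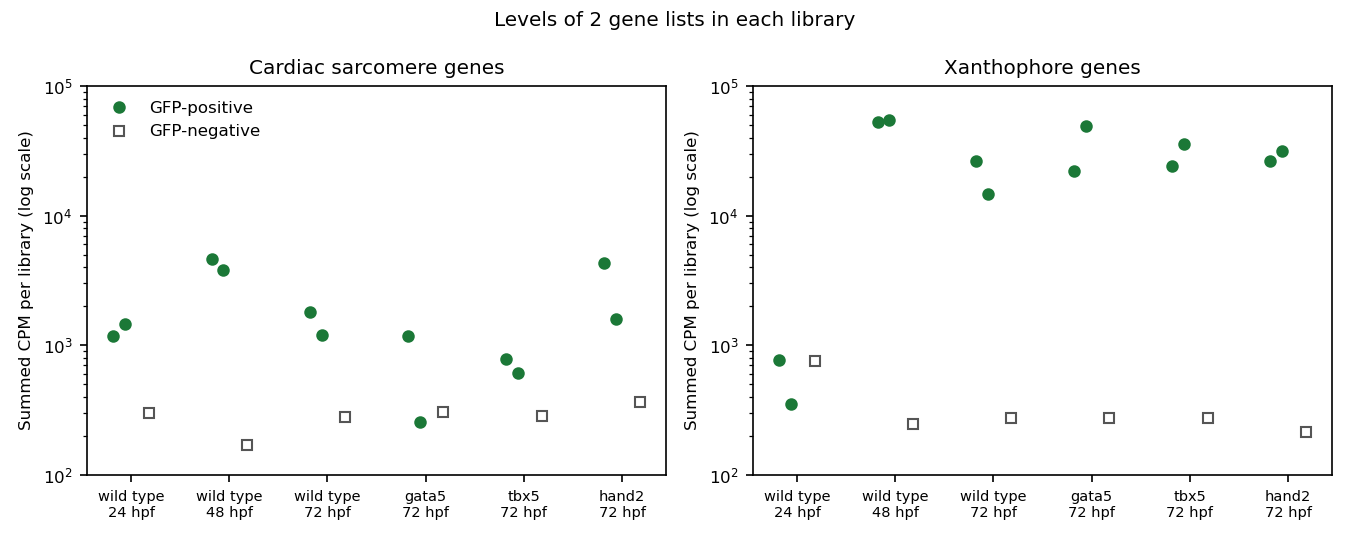
Summed CPM (y axis, log scale) of the cardiac sarcomere genes and of the xanthophore genes in each library, by condition, with filled circles for GFP-positive and open squares for GFP-negative libraries. Sarcomere sums of GFP-positive libraries run from 258 CPM in gata5 replicate 2 to 4599 in a 48 hpf library, and xanthophore sums of those at 48 and 72 hpf from 14700 to 54400.

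**Figure D3:**
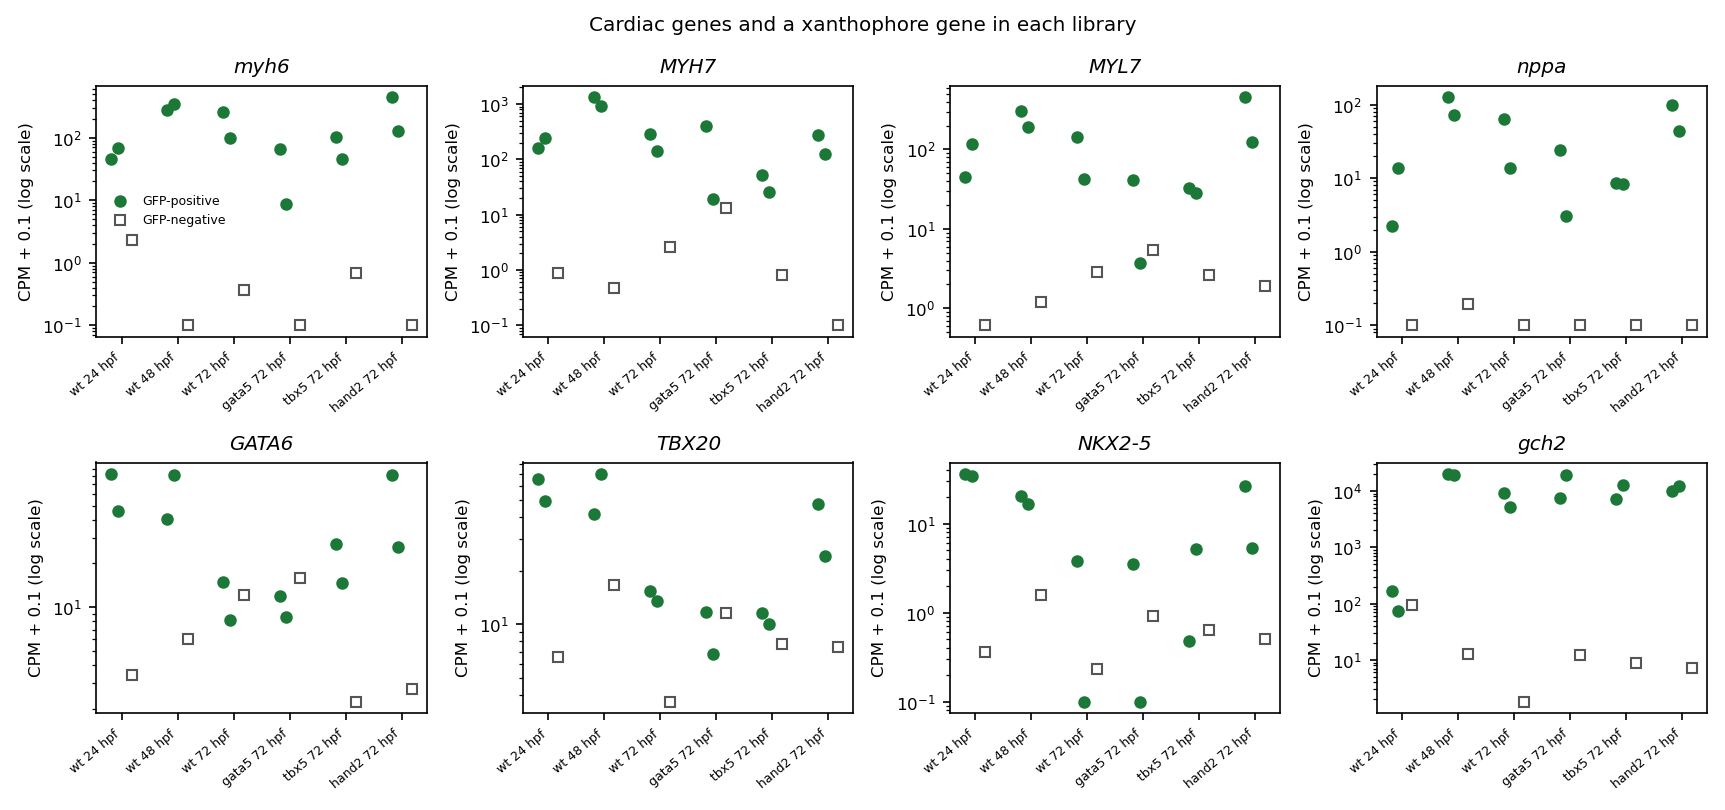
CPM plus 0.1 (y axis, log scale) of 7 cardiac genes and of gch2 in each library, by condition (x axis), with filled circles for GFP-positive and open squares for GFP-negative libraries. The mean of myh6 is 158 CPM in GFP-positive and 0.504 in GFP-negative libraries, and gch2 is low in the GFP-positive libraries at 24 hpf (mean 121 CPM).

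Between 24 and 48 hpf, cell cycle, blood and endothelial transcripts fell in the wild-type GFP-positive fraction (n = 2 at each stage). Markers of other cell types rose in it over the same interval, so a changed make-up cannot be told apart from a change within cells. From 24 to 72 hpf the single GFP-negative libraries fell too, with medians of −1.479 for cell cycle, −1.779 for erythrocyte and −1.905 for endothelial genes. Against the wild-type GFP-negative library at 72 hpf, those of the genotypes had medians of 1.18 to 1.535 for erythrocyte genes. For endothelial genes these were −0.018 to 1.349, and for cell cycle genes −0.686 to −0.54. The GFP-negative falls in erythrocyte and endothelial genes may thus rest partly on that wild-type library. Cell cycle genes fell in 43 of 48 members and rose in 0, 44 and 0 adjusted over the list alone, with a median of −2.43 (adjusted p = 2.1e-42), and the call held with an estimated correlation (adjusted p = 0.00141). CCND1, the cyclin of the G1 phase, went from 835 to 90.4 CPM (−3.24 ± 0.31), and CDT1, which licenses replication origins, fell too (−3.44 ± 0.50). Ribosome biogenesis genes fell in 16 of 26 and rose in 0, 19 and 0 adjusted over the list alone (median −1.45, adjusted p = 1.62e-13, adjusted p = 0.0567 with an estimated correlation), BOP1 among them (−3.0 ± 0.39). Erythrocyte genes fell in 12 of 16 and rose in 1, 15 and 1 adjusted over the list alone (median −3.92, adjusted p = 1.06e-17, adjusted p = 0.00141 with an estimated correlation), with the globin hbbe3 (−6.36 ± 1.43) and the transferrin receptor tfr1a (−7.62 ± 1.38). Their summed level was 31690 and 33830 CPM in the 24 hpf libraries and 4407 and 3912 at 48 hpf. Endothelial genes fell in 17 of 24 and rose in 0, 21 and 0 adjusted over the list alone (median −4.03, adjusted p = 1.47e-21, adjusted p = 0.0317 with an estimated correlation). stab2, a scavenger receptor of vein and lymphatic endothelium, went from 1490 to 2.59 CPM (−9.21 ± 1.18), and lyve1b was at least 313-fold lower. Leukocyte genes fell in 6 of 18 and rose in 2, 7 and 2 adjusted over the list alone (median −2.38, adjusted p = 0.00355, adjusted p = 0.423 with an estimated correlation), npsn down and csf1ra up (5.60 ± 0.42).

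Some contractile and metabolic genes were higher at 48 hpf. The sarcomere list had a median of 2.18 (adjusted p = 0.000923, adjusted p = 0.488 with an estimated correlation), with 3 of 21 members called up, also adjusted over the list alone, and 0 down. These were MYOM2, which crosslinks thick filaments (2.57 ± 0.55), actn2b, alpha-actinin of the Z-disc (2.22 ± 0.52), and ldb3b (2.18 ± 0.64). MYL7 (1.58 ± 1.11, adjusted p = 0.431), MYH7 (2.43 ± 1.18, adjusted p = 0.262), myh6 (2.41 ± 1.01, adjusted p = 0.188) and nppa (3.61 ± 1.25, adjusted p = 0.112) were not called. Among cardiac transcription factors 1 of the MEF2C IDs fell (−1.12 ± 0.30), while gata4 (0.05), GATA6 (−0.12), TBX20 (−0.08), NKX2-5 (−0.96), HEY2 (−1.18), GATA5 (0.58), HAND2 (0.47) and TBX5 (1.36) were not called, nor was their list (adjusted p = 0.827). Glycolysis genes rose in 15 of 27 and fell in 0, 18 and 0 adjusted over the list alone (median 2.46, or 2.31 with genes absent from a group at their bound, adjusted p = 9.52e-11, adjusted p = 0.0567 with an estimated correlation). PKM, pyruvate kinase, was at least 239-fold higher. Fatty acid oxidation genes rose in 8 of 27, 9 adjusted over the list alone (median 0.76, bound 0.80, adjusted p = 0.00054, adjusted p = 0.0844 with an estimated correlation). Among them were PPARGC1A, a coactivator of mitochondrial biogenesis (3.53 ± 0.73), and CPT1B, 180-fold higher by pooled counts (61.3 to 876). Oxidative phosphorylation genes rose in 7 of 104, 5 adjusted over the list alone (median 0.61, adjusted p = 0.0424, adjusted p = 0.606 with an estimated correlation), and mitochondrially encoded transcripts in 4 of 13, 7 adjusted over the list alone (median 0.87, adjusted p = 0.00667, adjusted p = 0.486 with an estimated correlation). Clock genes rose in 12 of 20, 14 adjusted over the list alone (median 1.81, adjusted p = 2.15e-09, adjusted p = 0.0567 with an estimated correlation), BHLHE41 among them (6.40 ± 0.49).

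Other cell types gained transcripts in the sorted fraction at 48 hpf. Xanthophore genes rose in 21 of 22, 22 adjusted over the list alone (median 5.97, adjusted p = 8.37e-44, adjusted p = 0.0413 with an estimated correlation). slc22a7a went from 4.25 to 3910 CPM (9.81 ± 0.49), plin6 from 2.0 to 838 (8.65 ± 0.51), and the summed level of the list from 772 and 352 CPM to 52330 and 54440. The gene with the largest rise, oacyl, was at least 10200-fold higher. Neural crest and pigment genes rose in 5 of 13, also adjusted over the list alone (median 2.61, adjusted p = 6.22e-06, adjusted p = 0.0567 with an estimated correlation), with TYR, tyrosinase (5.78 ± 0.54), and SOX10 (4.61 ± 0.39). Iridophore genes rose in 3 of 10 (adjusted p = 0.00147, adjusted p = 0.0998 with an estimated correlation) and melanophore genes in 4 of 9 (adjusted p = 0.00472, adjusted p = 0.0547 with an estimated correlation), the same numbers adjusted over each list alone. Skeletal muscle genes rose in 17 of 25, 20 adjusted over the list alone (median 6.07, bound 5.51, adjusted p = 7.17e-24, adjusted p = 0.0567 with an estimated correlation), the parvalbumin pvalb2 being at least 1180-fold higher. Neural genes rose in 10 of 21, 13 adjusted over the list alone (median 3.18, adjusted p = 2.29e-09, adjusted p = 0.046 with an estimated correlation), NEUROD1 being at least 545-fold higher. Epidermis genes rose in 12 of 25 and fell in 1, the same adjusted over the list alone (median 3.67, adjusted p = 3.21e-07, adjusted p = 0.303 with an estimated correlation). Liver, yolk and gut genes rose in 12 of 23, 15 up and 2 down adjusted over the list alone (median 4.73, bound 3.61, adjusted p = 3.88e-08, adjusted p = 0.0567 with an estimated correlation). Epicardium and fibroblast-like genes rose in 8 of 23 and fell in 3, 8 and 4 adjusted over the list alone (median 0.85, adjusted p = 0.0209, adjusted p = 0.538 with an estimated correlation), with TBX18 (4.63 ± 0.67) and WT1, at least 437-fold higher. The lists of collagens (11 up and 1 down of 55, 14 and 3 adjusted over the list alone, median 0.98, bound 1.09), cartilage (4 up of 16, 7 adjusted over the list alone, median 2.63, bound 2.36) and lens and retina (5 up of 23, 7 adjusted over the list alone, median 5.19, bound 3.35) were called too. Their adjusted p were 0.0214, 0.00427 and 0.00696, against adjusted p = 0.606, 0.488 and 0.305 with an estimated correlation.

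In all 3173 of 23767 genes changed between 24 and 48 hpf, 2154 up and 1019 down, and 4 of 20 called lists held with an estimated correlation. Leaving out 48 hpf replicate 1 or replicate 2 gave 1881 and 1959 genes, and the DESeq2 test 5201. With the xanthophore level of each library as a covariate, chosen after seeing the data, 9 genes passed, and with the sarcomere level 1614. The xanthophore level itself separates these stages, so that fit sets the stage difference against the same covariate.

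From 48 to 72 hpf, the list calls of wild-type GFP-positive cells (n = 2 at each stage) that held with an estimated correlation were of liver-type and blood genes. Liver, yolk and gut genes rose in 7 of 23 and fell in 0, 14 and 0 adjusted over the list alone, with a median of 3.37 (adjusted p = 4.53e-30, adjusted p = 0.00717 with an estimated correlation). fabp10a, the liver fatty acid binding protein, was at least 451-fold higher, and the protease inhibitor serpina1l rose (4.51 ± 0.46, adjusted p = 0.000528). Erythrocyte genes fell in 3 of 16 and rose in 0, 5 and 0 adjusted over the list alone (median −1.42, adjusted p = 3.71e-07, adjusted p = 0.0218 with an estimated correlation), for example the globin gene hbae1.1 (−1.93 ± 0.35). Xanthophore genes had a median of −1.3, with 1 of 22 called down, 10 adjusted over the list alone (adjusted p = 8.69e-08, adjusted p = 0.402 with an estimated correlation). That gene was ATIC of purine synthesis (−2.49 ± 0.41), and QDPR, which recycles a pterin cofactor (−2.86 ± 0.41), fell too. Iridophore genes had a median of −0.92 and 1 of 10 called, pnp4a (−2.40 ± 0.48; adjusted p of the list 0.0135, adjusted p = 0.379 with an estimated correlation). Photoreceptor genes rose, opn1lw2 (5.55 ± 0.73) and GNAT2 (4.36 ± 0.85) in a lens and retina list with 2 of 23 up, 3 adjusted over the list alone (median 2.59, bound 2.46, adjusted p = 3.1e-05, adjusted p = 0.362 with an estimated correlation), and the cone gene gnb3b was at least 962-fold higher. elnb, an elastin of the outflow tract, rose (5.26 ± 1.0), as did COL8A2 (4.49 ± 0.65). DHX33 was at least 204-fold lower at 72 hpf and ZC3H12B 1090-fold by pooled counts (196 to 43300). The other 10 GFP-positive libraries, those of the genotypes at 72 hpf included, held these genes at medians of 14.2 and 14.5 CPM. Both genes were called higher in all 3 genotypes than in the same wild-type libraries. For these genes a change with stage thus cannot be told apart from a trait of the 2 wild-type libraries at 72 hpf.

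Cardiac lists were lower at 72 than at 48 hpf by camera only. The sarcomere list had a median of −1.2 with 0 of 21 members called, 2 down adjusted over the list alone (adjusted p = 0.00535, adjusted p = 0.526 with an estimated correlation). Cardiac transcription factors had a median of −0.95 with 0 of 23 called, 4 down adjusted over the list alone (adjusted p = 0.00112, adjusted p = 0.402 with an estimated correlation). TBX20 (−1.94 ± 0.47, adjusted p = 0.0861), GATA6 (−2.38 ± 0.59, adjusted p = 0.102), GATA5 (−1.68 ± 0.48, adjusted p = 0.159), gata4 (−1.80 ± 0.58, adjusted p = 0.228), NKX2-5 (−3.30), HEY2 (1.13), MYL7 (−1.41), MYH7 (−2.37), myh6 (−0.79) and nppa (−1.33) were not called. The summed sarcomere level was 4599 and 3818 CPM at 48 hpf and 1792 and 1203 at 72 hpf. Replicate 2 at 72 hpf stood apart in the levels of collagens (17010 against 6414 CPM in replicate 1), cartilage genes (9284 against 2603) and skeletal muscle genes (16550 against 4869). Collagens (median 0.67, adjusted p = 0.000205), cartilage genes (median 2.61, adjusted p = 4.38e-07) and skeletal muscle genes (median 0.79, adjusted p = 0.000284) were called up by camera. With an estimated correlation they had adjusted p = 0.418, 0.383 and 0.418.

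Between 48 and 72 hpf 116 genes changed, 62 up and 54 down, with 2716 at an unadjusted p under 0.05. Leaving out 48 hpf replicate 1 gave 47 genes, 48 hpf replicate 2 gave 26 and 72 hpf replicate 1 gave 765, of which 175 were up and 590 down, the opposite balance. The DESeq2 test gave 1330 genes and the fit of only the compared libraries gave 0.

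Over the whole interval from 24 to 72 hpf (n = 2 at each stage), 3743 of 23767 genes changed, 2412 up and 1331 down. The falls in cell cycle (40 of 48 members, 42 adjusted over the list alone, median −2.28, adjusted p = 6.15e-31, adjusted p = 0.00296 with an estimated correlation) and erythrocyte genes (14 of 16 with 1 up, 15 and 1 adjusted over the list alone, median −5.84, adjusted p = 5.44e-22, adjusted p = 0.00207 with an estimated correlation) were again among them. hbbe3 was at least 66300-fold lower, and gata1a, the regulator of red cell genes, at least 2890-fold. Endothelial genes fell in 16 of 24 and rose in 1, 19 and 1 adjusted over the list alone (median −3.0, adjusted p = 1.01e-13, adjusted p = 0.0497 with an estimated correlation), EGFL7 among them (−9.55 ± 1.11). Liver genes rose in 18 of 23, 20 up and 2 down adjusted over the list alone (median 8.82, bound 7.21, adjusted p = 6.98e-24, adjusted p = 0.0105 with an estimated correlation). Clock genes rose in 13 of 20, 15 adjusted over the list alone (median 1.73, adjusted p = 5.59e-12, adjusted p = 0.0492 with an estimated correlation), neural genes in 11 of 21, 14 up and 1 down adjusted over the list alone (median 3.90, adjusted p = 8.33e-08, adjusted p = 0.0492 with an estimated correlation), and fatty acid oxidation genes in 9 of 27, 10 adjusted over the list alone (median 0.99, adjusted p = 4.31e-06, adjusted p = 0.0497 with an estimated correlation). CPT1B was 340-fold higher by pooled counts (116 to 1650).

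Cardiac transcription factors were lower at 72 than at 24 hpf as a list, with 3 of 23 members down and 1 up, 4 and 1 adjusted over the list alone (median −0.47, adjusted p = 0.0231, adjusted p = 0.352 with an estimated correlation). GATA6 (−2.50 ± 0.59, adjusted p = 0.0101), TBX20 (−2.02 ± 0.47, adjusted p = 0.00846) and 1 of the MEF2C IDs (−1.46 ± 0.30, adjusted p = 0.00368) fell, and ISL1, a factor of late-added heart cells, rose (2.27 ± 0.63). Neither gata4 (−1.75 ± 0.58, adjusted p = 0.0544), NKX2-5 (−4.26), HEY2 (−0.05), MYL7 (0.18), MYH7 (0.06), myh6 (1.62) nor nppa (2.28) was called. The sarcomere list was not called (3 up and 1 down of 21, median 0.79, adjusted p = 0.164). Epicardium and fibroblast-like genes rose in 8 of 23 and fell in 3, 10 and 4 adjusted over the list alone (median 1.11, adjusted p = 0.00378, adjusted p = 0.352 with an estimated correlation), COL1A1 among the higher ones (4.35 ± 0.51). Smooth muscle genes rose in 4 of 7, also adjusted over the list alone (median 1.89, adjusted p = 0.0268, adjusted p = 0.25 with an estimated correlation), acta2 among them (4.08 ± 0.78). Xanthophore genes rose in 19 of 22, 21 adjusted over the list alone (median 4.83, adjusted p = 3.18e-31, adjusted p = 0.0531 with an estimated correlation). The DESeq2 test called 6515 genes, the 6 wild-type libraries alone 2227, the compared libraries alone 763 and the fit with the xanthophore level as a covariate 104.

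**Figure D4:**
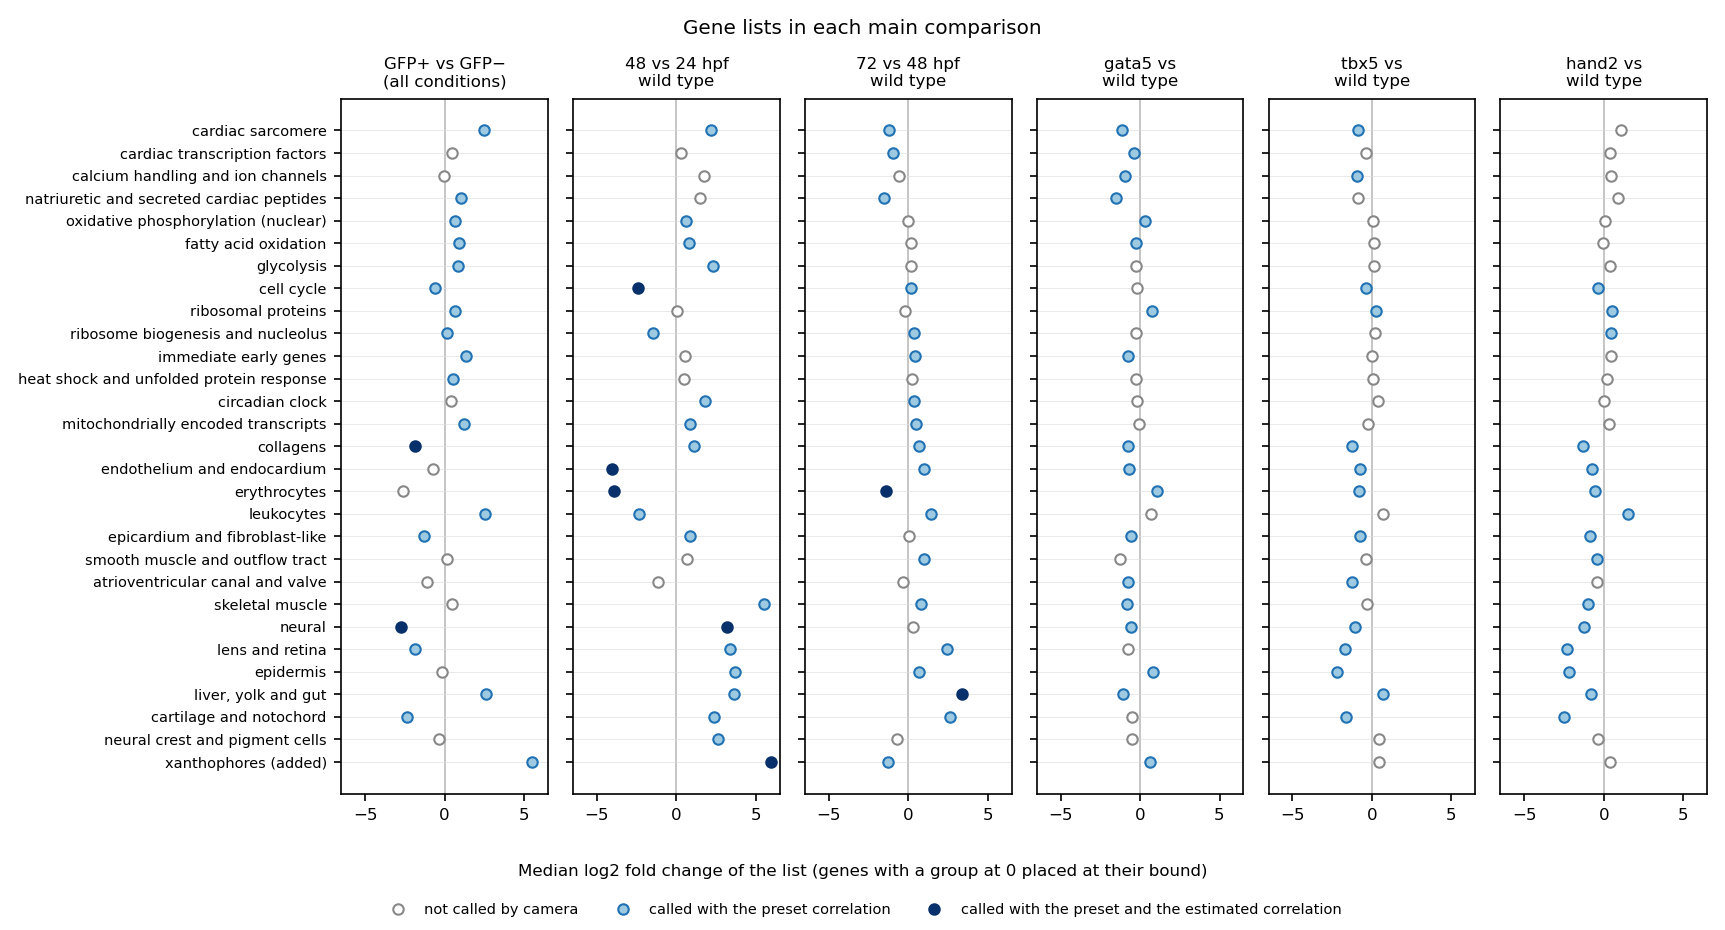
Median log2 fold change (x axis) of the gene lists reported (y axis) in 6 of the main comparisons, 1 panel each, with genes absent from a group placed at their bound. Open points were not called by camera, light points were called with the preset correlation and dark points also with the estimated one, among them cell cycle genes at 48 against 24 hpf (median −2.43).

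In gata5 at 72 hpf, the GFP-positive cells (n = 2 against 2 wild-type libraries) held less of some liver-type transcripts. tfa, transferrin, stood at 105 against 499 CPM (−2.27 ± 0.29, adjusted p = 0.00484), serpina1, a liver protease inhibitor, at 23.8 against 108 (−2.20 ± 0.37, adjusted p = 0.0398), and the clotting factor gene f8 lower too (−3.01 ± 0.51). Of the liver, yolk and gut list 2 of 23 fell and 0 rose, 7 and 0 adjusted over the list alone (median −1.09, adjusted p = 6.51e-11, adjusted p = 0.0881 with an estimated correlation). GLDC of glycine breakdown (2.66 ± 0.36, adjusted p = 0.00921), the antioxidant gene prdx1 (2.04 ± 0.31) and TSC1, a brake on growth signalling (1.94 ± 0.28), rose. A pair of IDs with the symbol KCNJ1 were at least 756-fold and 660-fold higher, and ZC3H12B was 655-fold higher by pooled counts (116 to 26000). The cardiac sarcomere list had a median of −1.13 with 0 of 21 members called, 0 also adjusted over the list alone (adjusted p = 2.02e-08, adjusted p = 0.399 with an estimated correlation). Its summed level was 1186 and 258 CPM in gata5 and 1792 and 1203 in wild type, and without gata5 replicate 2 the median was −0.54. MYL7 (−2.06 ± 1.14, adjusted p = 0.567), myh6 (−2.25 ± 1.01, adjusted p = 0.526), MYH7 (−0.06), nppa (−1.50), TBX20 (−0.66), gata4 (−0.93), GATA6 (−0.19), NKX2-5 (−0.09), HEY2 (−1.21) and a MEF2C ID (−1.71 ± 0.37, adjusted p = 0.112) were not called. Camera also called cardiac transcription factors (median −0.37, adjusted p = 0.00761), calcium handling genes (−0.92, adjusted p = 0.0121), natriuretic peptides (−1.27, bound −1.50, adjusted p = 0.0209) and fatty acid oxidation genes (−0.24, adjusted p = 0.00846) lower, each with adjusted p = 0.399 with an estimated correlation. Ribosomal protein genes were higher (median 0.78, adjusted p = 7.44e-15, adjusted p = 0.399 with an estimated correlation), with 0 of 93 called and 15 adjusted over the list alone. Erythrocyte genes were higher (median 1.07, adjusted p = 0.000292, adjusted p = 0.0881 with an estimated correlation), with 0 of 16 called and 5 adjusted over the list alone. Epidermis genes, whose summed level was 42450 CPM in replicate 1 and 12170 in replicate 2, had a median of 0.82 (adjusted p = 0.0128, adjusted p = 0.515 with an estimated correlation). Their summed level in gata5 replicate 2 lies below that of wild-type replicate 2, which is given below for hand2.

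For gata5, 25 genes were called, 18 up and 7 down, with 2290 at an unadjusted p under 0.05. In the simulated data 18.6% of the calls of this comparison were false. Leaving out gata5 replicate 2 gave 6 genes, wild-type replicate 1 gave 573 and wild-type replicate 2 gave 59, while the DESeq2 test gave 1007 and the compared libraries alone 0. Of the 18 higher calls, 10 had at most 3 counts over both wild-type libraries. Camera called 13 lists lower and 4 higher in gata5, not all of them named here, and no call held with an estimated correlation. Among the lists of other cell types compared, median log2 levels differed from wild type by −1.089 (SE 0.717, lens and retina) to 0.527 (SE 0.523, erythrocytes).

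In tbx5 (n = 2 against 2), 11 genes were called, 10 up and 1 down. The 1 lower gene was heg1, an endocardial receptor needed for heart growth, at 5.41 against 35.4 CPM (−2.71 ± 0.43, adjusted p = 0.039). TSC1 rose (1.93 ± 0.28, adjusted p = 0.0209), DHX33 was at least 226-fold higher and ZC3H12B 893-fold by pooled counts (160 to 35300). The sarcomere list had a median of −0.89 with 0 of 21 called, 0 also adjusted over the list alone (adjusted p = 0.00018, adjusted p = 0.443 with an estimated correlation), and summed levels of 784 and 611 CPM. MYH7 (−2.48 ± 1.19, adjusted p = 0.612), nppa (−2.21), MYL7 (−1.60), myh6 (−1.25), TBX20 (−0.43), gata4 (−0.14), GATA6 (0.86), NKX2-5 (0.55), HEY2 (−1.06) and a MEF2C ID (1.19 ± 0.30, adjusted p = 0.281) were not called. Atrioventricular canal genes had a median of −1.23 with 0 of 11 called, 2 adjusted over the list alone (adjusted p = 3.89e-05, adjusted p = 0.25 with an estimated correlation). Cell cycle genes were slightly lower (median −0.33, adjusted p = 0.000162, adjusted p = 0.25 with an estimated correlation). Liver genes were higher (median 0.69, adjusted p = 0.00199, adjusted p = 0.25 with an estimated correlation), with 0 of 23 called and 5 adjusted over the list alone. Collagens (median −1.21, adjusted p = 4.87e-10), epicardium and fibroblast-like genes (−0.78, adjusted p = 1.99e-07), cartilage genes (−1.55, bound −1.66, adjusted p = 9.67e-07) and epidermis genes (−2.18, adjusted p = 1.63e-08) were lower by camera. With an estimated correlation they had adjusted p = 0.25, 0.25, 0.25 and 0.258. The wild-type libraries themselves differed in collagen and cartilage levels, as given above for 72 hpf, and in epidermis levels, as given below for hand2. Erythrocyte genes, called lower (adjusted p = 0.00199, adjusted p = 0.25 with an estimated correlation), had a median of −0.83 and a mean of 0.13.

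For tbx5, 1983 genes had an unadjusted p under 0.05. Leaving out tbx5 replicate 1 or 2 gave 4 genes each, wild-type replicate 1 gave 475 and wild-type replicate 2 gave 21, while the DESeq2 test gave 744 and the compared libraries alone 0. Of the 10 higher calls, 8 had at most 3 counts over both wild-type libraries.

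In hand2 (n = 2 against 2), 12 genes were called, 8 up and 4 down. Cone photoreceptor genes were lower, gnb3b at 1.4 against 84.8 CPM (−5.91 ± 0.66, adjusted p = 0.00508) and opn1lw2 at 2.78 against 86.9 (−4.97 ± 0.70, adjusted p = 0.0232), as were f8 (−4.88 ± 0.56, adjusted p = 0.00288) and FBXO8 (−7.61 ± 1.2). DHX33 was at least 271-fold higher and ZC3H12B 691-fold by pooled counts (123 to 27300). The sarcomere list was not called (median 1.09, adjusted p = 0.126, 0 of 21 called and 1 up adjusted over the list alone), with summed levels of 4329 and 1588 CPM. MYL7 (1.66 ± 1.12, adjusted p = 0.634), gata4 (2.0 ± 0.58, adjusted p = 0.275), GATA6 (2.23 ± 0.59, adjusted p = 0.221), TBX20 (1.31, adjusted p = 0.401), NKX2-5 (3.11), HEY2 (−1.79), a MEF2C ID (1.01), myh6 (0.68), MYH7 (−0.10) and nppa (0.90) were not called. Leukocyte genes were higher (median 1.51, adjusted p = 2.22e-05, adjusted p = 0.251 with an estimated correlation), with 0 of 18 called and 3 adjusted over the list alone, and so were ribosomal protein genes (median 0.49, adjusted p = 5.68e-07, adjusted p = 0.565 with an estimated correlation), with 0 of 93 called and 10 adjusted over the list alone. Lens and retina genes were lower (median −3.23, bound −2.32, adjusted p = 7.33e-10, adjusted p = 0.0987 with an estimated correlation), with 1 of 23 called and 2 adjusted over the list alone. Neural genes (median −1.25, adjusted p = 5.68e-07) and cell cycle genes (−0.38, adjusted p = 4.96e-07) were lower, both with adjusted p = 0.0987 with an estimated correlation. Collagens (median −1.32, adjusted p = 1.08e-12, 6 down adjusted over the list alone), cartilage genes (−2.50, adjusted p = 1.19e-10, 5 down), epicardium and fibroblast-like genes (−0.84, adjusted p = 2.34e-09, 6 down), skeletal muscle genes (−0.99, adjusted p = 3.95e-06, 2 down) and epidermis genes (−2.21, adjusted p = 2.01e-10) were lower by camera. With an estimated correlation they had adjusted p = 0.222, 0.158, 0.158, 0.381 and 0.237. Wild-type replicate 2 stands above replicate 1 in skeletal muscle (16550 against 4869 CPM), epidermis (12560 against 5287) and collagen genes (17010 against 6414). Both hand2 libraries (6324 and 5068 CPM) lie above replicate 1 for skeletal muscle genes, so that fall rests on replicate 2. Erythrocyte genes, called lower (adjusted p = 0.00153, adjusted p = 0.0987 with an estimated correlation), had a median of −0.53 and a mean of 0.49.

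For hand2, 2160 genes had an unadjusted p under 0.05. Leaving out hand2 replicate 1 gave 3 genes, hand2 replicate 2 gave 7 and wild-type replicate 1 gave 543, while the DESeq2 test gave 806 and the compared libraries alone 0. Of the 8 higher calls, 7 had at most 3 counts over both wild-type libraries.

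The stage change of wild type was looked for in the genotypes with the genes called between 24 and 48 hpf, a list taken from libraries outside these contrasts. The 1019 genes lower at 48 hpf were lower in gata5 (median −0.11, adjusted p = 0.0262, adjusted p = 0.428 with an estimated correlation) and tbx5 (median −0.10, adjusted p = 0.00191, adjusted p = 0.323 with an estimated correlation) and were not called in hand2 (adjusted p = 0.0769). The 2154 genes higher at 48 hpf were called lower in hand2, where their median of 0.03 and mean of −0.15 differ in sign (adjusted p = 0.0115, adjusted p = 0.423 with an estimated correlation), and not in gata5 (adjusted p = 0.35) or tbx5 (adjusted p = 0.819).

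The genotypes share their wild-type libraries, so their calls overlap by chance as well. 12 genes were called in 2 or more genotypes, where simulation of unchanged groups gave 0.5 on average and 2 at most. In 3 genotypes 7 genes were called, where simulation gave 0.167. All libraries at 72 hpf, wild type included, were redrawn in it from a common mean per gene. The simulated genotypes shared a simulated wild-type pair, so the simulation does not show what traits of the real pair alone would give. Among the shared genes were DHX33, ZC3H12B, uros and hdr, called higher in all 3 genotypes, and gnb3b and f8, called lower in gata5 and hand2. All 7 genes called in 3 genotypes averaged 0 to 0.117 CPM in the wild-type GFP-positive libraries at 72 hpf. The wild-type GFP-negative library held them at 5.8 to 28.5 CPM. Of the genes called in 2 genotypes, gnb3b, f8 and TSC1 averaged 84.8, 92.1 and 47.7 CPM in the wild-type GFP-positive libraries. Log2 fold changes correlated across genes with r = 0.599 for gata5 and tbx5, 0.643 for gata5 and hand2 and 0.741 for tbx5 and hand2, against 0.484, 0.485 and 0.495 in simulation. Covariances were 5.07, 5.30 and 5.75 against 2.01, 2.02 and 2.01. The pairs shared 10, 9 and 7 called genes, where independent lists would share 0.00787, 0.00724 and 0.00353. The 2 wild-type libraries cannot be divided into groups of 2, so how much of the excess comes from them was not tested.

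Compared with each other (n = 2 each), the genotypes differed in liver and blood genes by the list calls that held with an estimated correlation. Between gata5 and tbx5, 9 genes differed, 1 higher and 8 lower in gata5. The liver genes serpina1l (39.2 against 494 CPM, −3.66 ± 0.44), tfa (105 against 810 CPM, −2.97 ± 0.30, adjusted p = 0.00153) and PLG, plasminogen (−3.72 ± 0.53), were lower and HBE1, a globin, was higher (2.91 ± 0.40, 223 against 29.5 CPM). The liver list had 3 of 23 lower, 15 adjusted over the list alone (median −2.67, adjusted p = 9.06e-27, adjusted p = 0.00511 with an estimated correlation), and the erythrocyte list 0 of 16, 8 higher adjusted over the list alone (median 1.96, adjusted p = 5.29e-16, adjusted p = 0.00471 with an estimated correlation). Between gata5 and hand2, 2 genes differed, 1 higher and 1 lower in gata5. The lower one was PPOX of heme synthesis, named after its values were seen, at 0 CPM in both gata5 libraries and 2.52 and 2.75 in hand2. RLE scaling gave 3 higher and 1 lower where TMM gave 1 and 1. The sarcomere list had a median of −2.50 in gata5 against hand2 (0 of 21 called, 12 lower adjusted over the list alone, adjusted p = 2.35e-15, adjusted p = 0.141 with an estimated correlation), and erythrocyte genes a median of 1.54 (0 of 16 called, 7 higher adjusted over the list alone, adjusted p = 6.98e-16, adjusted p = 0.0041 with an estimated correlation). Between tbx5 and hand2, tfa alone was called, higher in tbx5 (810 against 171 CPM, 2.24 ± 0.29, adjusted p = 0.0396). Liver genes were higher in tbx5 (1 of 23 called, 4 adjusted over the list alone, median 1.37, bound 1.3, adjusted p = 9.87e-17, adjusted p = 0.0289 with an estimated correlation) and sarcomere genes lower (median −1.79, 0 of 21 called, 2 adjusted over the list alone, adjusted p = 1.08e-11, adjusted p = 0.365 with an estimated correlation). Genes at an unadjusted p under 0.05 numbered 1264, 1431 and 651 in these contrasts, DESeq2 called 286, 280 and 58, and the bias-adjusted fit 103, 54 and 22.

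Whether the change from 24 to 72 hpf differed between GFP-positive and GFP-negative cells was tested as an interaction (2 against 1 library at each stage). 402 of 26357 genes differed, 330 with a larger rise in GFP-positive cells and 72 with a smaller one, and 2347 had an unadjusted p under 0.05. Xanthophore genes were among them, slc22a7a (16.22 ± 0.91), plin6 (14.83 ± 1.46) and gch2 (11.65 ± 1.23), with 14 of 22 called up, 20 adjusted over the list alone (median 5.77, adjusted p = 5.8e-29, adjusted p = 0.115 with an estimated correlation). Melanophore genes had 4 of 9 up, 7 adjusted over the list alone (median 7.96, adjusted p = 2.44e-06, adjusted p = 0.0294 with an estimated correlation), TYR among them (8.37 ± 0.93). Skeletal muscle genes had 7 of 25 up, 17 adjusted over the list alone (median 6.13, adjusted p = 1.99e-16, adjusted p = 0.18 with an estimated correlation), and neural genes 3 of 21 up and 1 down, 9 and 1 adjusted over the list alone (median 3.35, adjusted p = 8.25e-07, adjusted p = 0.117 with an estimated correlation). Erythrocyte genes fell more in GFP-positive cells, with 5 of 17 down, 9 adjusted over the list alone (median −3.55, adjusted p = 4.48e-08, adjusted p = 0.0214 with an estimated correlation), hbae1.1 among them (−4.08 ± 0.59). GATA6 (−4.35 ± 1.08) and BMP4 (−3.53 ± 0.81) also fell more there. In the simulated data 60.8% of such calls were false, and the bias-adjusted fit called 171 genes, of which 134 were shared.

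Genotype effects that differed between GFP-positive and GFP-negative cells were few. They numbered 8 for gata5 (6 up, 2 down), 13 for tbx5 (10 up, 3 down) and 27 for hand2 (12 up, 15 down), and 1029, 1083 and 1491 at an unadjusted p under 0.05. NPAS4, an immediate early transcription factor of neurons, had a negative interaction in gata5 (−5.65 ± 0.95), tbx5 (−7.64 ± 0.99) and hand2 (−7.59 ± 0.99), and immediate early genes had medians of −2.44, −2.42 and −1.78 (adjusted p = 4.95e-11, 1.77e-09 and 6.95e-07, and adjusted p = 0.397, 0.68 and 0.576 with an estimated correlation). Of that list 0 of 21 members were called in each, and 1, 5 and 1 lower adjusted over the list alone. The other lower gene in gata5 was PPOX, named after its values were seen. egr4 (−6.74 ± 1.13) and spega (−5.73 ± 0.94) were the other genes lower in tbx5. These 3 interactions share the single wild-type GFP-negative library at 72 hpf, where immediate early genes summed to 399 CPM against 1238, 2424 and 2278 in the gata5, tbx5 and hand2 ones, and they rest on it in common. For the liver list given next, the single tbx5 GFP-negative library had a median log2 ratio of −2.194 against this wild-type library. In tbx5 the liver list was higher, with 4 of 27 called, 6 adjusted over the list alone (median 3.07, adjusted p = 2.84e-06, adjusted p = 0.0841 with an estimated correlation), serpina1 among them (4.82 ± 0.72). In hand2, hbae3 (−3.35 ± 0.60) and hbae1.1 (−3.06 ± 0.58) were lower, in an erythrocyte list with 2 of 17 down, 7 adjusted over the list alone (median −2.51, adjusted p = 7.76e-06, adjusted p = 0.0523 with an estimated correlation). In hand2 the all-gene median was 0.20 with TMM and 0.07 with RLE scaling, so changes there are relative to that shift. RLE scaling gave 6 up and 4 down for gata5 and 7 up and 15 down for hand2. The bias-adjusted fit called 0 genes for gata5, with 769 at an unadjusted p under 0.05, 31 for tbx5 (7 up, 24 down) and 37 for hand2 (2 up, 35 down), turning the balance in tbx5, and DESeq2 called 139, 180 and 281.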

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

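The tests of pigment cells in the gate and of chance drop-out by the plain product were chosen before the result they measure was seen. The tests of transcripts carried by cardiomyocytes, free RNA, 1 gata5 library, a smaller share of cardiomyocytes, drop-out with genes matched for level, a sequence variant and loss at 72 hpf were chosen after it was seen, as was the xanthophore list.

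The change from 24 to 72 hpf differed between GFP-positive and GFP-negative cells for 402 genes by an interaction test, with slc22a7a, plin6, gch2 and other xanthophore genes among them. Over the 8 GFP-positive libraries at 72 hpf, the 22 xanthophore genes stayed near the mean of the other listed genes in each library. The median SD of their log2 levels about it was 0.309, against 0.784 for 16 sarcomere genes about theirs. Pigment cells in the gate need this, but any 1 cell type carrying these genes would also give it, as would genes that vary little. Transcripts carried by cardiomyocytes need a slope of 1 between xanthophore and sarcomere levels, if sarcomere transcripts per cardiomyocyte are alike in all libraries. The slope was −0.216 (−0.37 to −0.0266 with 1 library left out), which argues against this source under that condition only. The condition was not tested. Free RNA from all cells is argued against by xanthophore levels. The lowest GFP-positive library at 48 or 72 hpf (14700 CPM) lay 19.4 times above the highest GFP-negative one (757 CPM). Pigment cells inside the GFP gate may be the source, since xanthophores hold fluorescent pteridines, and a gate on a second channel would remove them (gch2 averaged 12300 CPM and csf1ra, the 1 gene also in another list, 2090 CPM). A change of xanthophores with stage, which the design names, stays open as an untested biological part of the difference. In GFP-positive libraries at 24 hpf, 13 of the 22 genes reached 10 CPM. Beside the GFP-negative libraries of all conditions, some of the genes were higher there (gch2, 121 against 22.4 CPM) and others lower (slc22a7a, 4.25 against 5.68 CPM). The 24 hpf libraries alone were not tested, so these levels do not show whether xanthophores were in the gate then.

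The effect of the genotype differed between GFP-positive and GFP-negative cells, by an interaction test, for 8 genes in gata5, 13 in tbx5 and 27 in hand2, and DHX33, ZC3H12B and uros are among the genes of each. These genes were missing from the GFP-positive wild-type libraries at 72 hpf. There 34 genes were missing from both, against 26.4 if the libraries lost genes independently within 20 classes of level, a ratio of 1.29. Chance drop-out may thus be the source for the 34 genes as a set. The ratio does not settle this for DHX33 and ZC3H12B singly, whose medians in the other 10 libraries were 14.2 and 14.5 CPM. For the set, the ratio of 5.56 to the plain product of shares (6.12) does not exclude chance drop-out, because genes of low level drop out together. A sequence variant of the wild-type fish is argued against by their median log2 ratio of 0.02 between the wild-type and the other GFP-negative libraries at 72 hpf, while the median of −0.185 between the genotypes at 72 hpf and wild type at 48 hpf decides nothing about loss at this stage, since the genes were chosen as present in the genotype libraries. A biological difference between the genotypes and wild type stays open and untested.

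The genotypes differed from each other in 9 genes (gata5 against tbx5), 2 (gata5 against hand2) and 1 (tbx5 against hand2), each by a direct test of the difference. The pattern weighed beside them is the lower sarcomere level in gata5, where the list median was −1.13, −0.542 without gata5 replicate 2 and −3.05 without replicate 1, −1.18 and −1.40 without wild-type replicate 1 or 2, and −0.71 without the libraries in doubt. The fall was smaller, and still a fall, in both fits without gata5 replicate 2, a library with few cardiac transcripts. Its size thus depends in part on that library. An uneven sort could give such a library and was not tested. A smaller share of cardiomyocytes cannot be told apart from a change within them, because the lists of other cell types gave no pair that moved apart past correction (lowest adjusted p = 0.335 over 55 pairs, 6 at an unadjusted p under 0.05, that of lowest p being endothelium minus erythrocytes at −1.43). An effect of gata5 on the number or state of cardiomyocytes stays open and untested.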

How the results depend on the processing

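The bias-adjusted fit, the sarcomere and xanthophore covariates, and the fits without the libraries in doubt or without the 24 hpf libraries were chosen after the results were seen. Over the alternatives, 6161 values of the named genes kept their side of the threshold in 5257 cases, lost the call in 831, gained one in 65 and reversed in 8. A reversal was counted only for a gene called in either fit, and 87 of the 5257 are genes called in neither whose sign changed. Of 169 counts, 77 stayed within 1.5 times the reported one and 92 moved. Unless a cause is given, the cause was not tested.

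GFP-positive against GFP-negative cells gave 6363 genes, 686 among the 9 wild-type libraries and 7269 without the 24 hpf libraries. The bias-adjusted fit gave 8181, DESeq2 8920, limma on the deposited log2 values 8135 and RLE scaling 6474. Without the condition covariate the count was 4573 (2335 higher and 2238 lower, where the reported balance is 2699 and 3664). Leaving out 1 GFP-negative library at a time gave 4462 to 6791.

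With 1 GFP-positive library left out at a time, counts ran from 1881 to 3074 for 48 against 24 hpf, 26 to 765 for 72 against 48 hpf, 2911 to 3990 for 72 against 24 hpf, 6 to 573 for gata5, 4 to 475 for tbx5 and 3 to 543 for hand2, with 0 opposite calls. A group left with 1 library was assumed to vary like the others.

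DESeq2 called more genes, 5201 for 48 against 24 hpf, 1330 for 72 against 48 hpf, 6515 for 72 against 24 hpf, 1007 for gata5, 744 for tbx5, 806 for hand2, 286 for gata5 against tbx5, 280 for gata5 against hand2, 58 for tbx5 against hand2, 1204 for stage by GFP, and 139, 180 and 281 for gata5, tbx5 and hand2 by GFP. Without the low-count filter the counts were 1022 for 72 against 48 hpf, 514, 407 and 507 for gata5, tbx5 and hand2, 350, 483 and 174 (68 up, 106 down) for gata5 against tbx5, gata5 against hand2 and tbx5 against hand2, 682 for stage by GFP, and 41, 102 and 127 by GFP.

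The bias-adjusted fit gave 553 for 72 against 48 hpf, 110 for gata5, 69 for tbx5, 245 for hand2, 103, 54 and 22 between the genotypes, 171 for stage by GFP, 31 for tbx5 by GFP (7 up, 24 down, against 10 and 3) and 0 for gata5 by GFP, where 769 genes had an unadjusted p under 0.05. Limma on the deposited log2 values gave 272 for 72 against 48 hpf, 88 for gata5, 30 for tbx5 and 53 for hand2. All libraries as 12 groups gave 43, 28 and 61 for gata5, tbx5 and hand2. RLE scaling gave 4 for gata5 against hand2. A fold minimum of 2 left all 14 counts within 1.5 times.

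Fitting only the compared libraries leaves few degrees of freedom. edgeR then called 0 genes for 72 against 48 hpf (2582 at an unadjusted p under 0.05), gata5 (936), tbx5 (1631), hand2 (2605), gata5 against tbx5 (1429) and gata5 against hand2 (2230), 10 for tbx5 against hand2 and 763 for 72 against 24 hpf. The 6 wild-type GFP-positive libraries alone gave 13 for 72 against 48 hpf and 2227 for 72 against 24 hpf.

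With the sarcomere level as a covariate the counts were 1614 for 48 against 24 hpf, 11 for gata5 and 4 for tbx5, and MYH7 reversed at 72 against 24 hpf (−1.90, adjusted p = 0.0205). With the xanthophore level they were 9 for 48 against 24 hpf, 17 for 72 against 48 hpf, 104 for 72 against 24 hpf and 4 for tbx5. Reversed, and not called, were PFKM (−0.78), PER1 (−2.88), npsn (2.27), XDH (−1.94) and SLC45A2 (−0.68) at 48 against 24 hpf, and sncb (−2.27) and XDH (−0.93) at 72 against 24 hpf. This covariate takes up the stage difference by construction. Without the libraries in doubt, the counts were 51 for gata5, 19 for tbx5, 15 for hand2, 4115 for 48 against 24 hpf, 160 for 72 against 48 hpf and 4039 for 72 against 24 hpf.

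List calls were repeated with an estimated correlation and with fry only. With an estimated correlation, 3 of 19 lists held for GFP, 4 of 20 for 48 against 24 hpf, 2 of 18 for 72 against 48 hpf, 7 of 20 for 72 against 24 hpf, 0 of 17, 0 of 14 and 0 of 15 for gata5, tbx5 and hand2, 2 of 13, 1 of 21 and 1 of 19 between the genotypes, 1 of 15 for stage by GFP, and 0 of 17, 0 of 15 and 0 of 10 by GFP. The fry test called 19, 19, 2, 20, 0, 0, 0, 2, 1, 0, 5, 0, 2 and 1 lists in these comparisons.

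With the replicate block the counts were 2965 for 48 against 24 hpf, 92 for 72 against 48 hpf, 3409 for 72 against 24 hpf, 19, 8 and 16 for gata5, tbx5 and hand2, 12 and 3 for gata5 against tbx5 and hand2, and 0 for tbx5 against hand2 (602 at an unadjusted p under 0.05). Residuals of libraries with the same replicate number correlated with r = −0.0871 to 0.0852 over 15 pairs (median 0.0186, 0 above 0.1), so the number carries no sign of a shared batch.

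Depth limits the calls of rare transcripts, with 5705157 to 18863332 counts in GFP-negative and 12070094 to 32141901 in GFP-positive libraries.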

Other observations

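The comparison of single GFP-negative libraries was chosen after the data were seen, and the test of other splits before its result was seen. With 1 GFP-negative library per condition there is no replicate, so list medians of log2 ratios were set against 10000 random lists of the same size and carry no test of the genotype. Against the wild-type library at 72 hpf, immediate early genes had medians of 1.63 in gata5, 2.42 in tbx5 and 2.29 in hand2, each at percentile 100, and erythrocyte genes 1.54, 1.26 and 1.18, also at percentile 100. Liver, yolk and gut genes had medians of −1.22, −2.19 and −1.46 (percentiles 0, 0 and 0.01), epidermis genes −0.89, −1.76 and −1.83 (percentile 0) and cell cycle genes −0.69, −0.66 and −0.54 (percentile 0). Neural genes had medians of 0.59, 0.89 and 0.56 (percentiles 100, 100 and 99.4), and endothelial genes 1.35, −0.02 and 0.60 (percentiles 100, 40 and 99.6). The same direction in 3 genotypes against 1 shared wild-type library is what that 1 library alone would also give.

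From 24 to 72 hpf in wild-type GFP-negative cells, liver genes had a median of 3.99, smooth muscle genes 3.20, cartilage genes 2.89, collagens 1.91, epicardium and fibroblast-like genes 1.44, glycolysis genes 1.3 and clock genes 1.19. Cell cycle genes had a median of −1.48, erythrocyte genes −1.78, endothelial genes −1.91 and neural crest and pigment genes −2.58. In GFP-positive cells neural crest and pigment genes instead had a median of 2.76 over the same interval.

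Splits of the 18 libraries within condition, which keep 1 library of each condition apart, number 729 with the real one, and 30 were drawn with the real one among them. The real split called 6363 genes and the highest of the others 379, and 1 of the 30 splits, the real one, called as many. With 30 of 729 splits drawn, this share could not fall below 1 in 30, and splits not drawn were not tested. The split with 379 genes kept 4 of the real GFP-negative libraries apart, and the other splits drawn kept at most 3.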
